A study of Mus musculus with 6 samples.

How the data were processed

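RNA from mouse embryonic stem (ES) cells was measured on 6 Illumina MouseWG-6 BeadChip arrays, 3 from control-transfected cells and 3 from cells transfected with a short hairpin RNA vector against Chd4 (shChd4). Per the labels' protocols, the cells grew with LIF and 15% serum on embryonic fibroblast feeders whose division had been blocked with mitomycin C. Plasmids were introduced by electroporation, and puromycin was applied from 24 h after transfection for 48 h. No sort is given, and the labels do not say whether the feeder cells resist puromycin or were removed. Total RNA was column-purified and amplified into biotin-labelled cRNA, per the labels' protocols. The titles place the 3 control arrays on 1 BeadChip and the 3 shChd4 arrays on another, so chip and group cannot be told apart. The labels carry no replicate numbers, and arrays are numbered here in accession order only as names. Nothing in the labels says that the arrays came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

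The deposited scanner table holds a linear intensity for each of 45281 probes on each array, and per the file headers a detection p-value for each probe and array. The submitters' processing notes name GenomeStudio, with no version. The intensity values of that table showed no background subtraction and no scaling between arrays, since their medians ranged from 110.9 to 118.9 and none lay near 0. The deposited series matrix holds a second set of intensity values from the authors for the same arrays. These had nearly identical quantiles on every array, with medians from 115.16 to 115.19, and a rank correlation of 1.00 with the scanner intensity of the same array. They are therefore on a linear scale, quantile-normalised and not background-subtracted; the method is not given in the sources used here. They served as an alternative.

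Background was corrected by normexp with background parameters inferred from the detection p-values, an offset of 16 was added, and arrays were quantile-normalised and put on a log2 scale, as in neqc of limma 3.58.1 under R 4.3.3. Probe names came from the platform annotation of GEO, in which 34885 probes have 1 gene symbol, 18 have several and 10378 are not named. Probes with several symbols or none were left out, among them 2359 unnamed probes that were detected in at least 3 arrays. Through Entrez identifiers, 34807 of the symbols were matched to a RefSeq gene table of assembly GRCm38.p6, which was used for names only, and 78 kept their older symbol. No coordinates are given because the sources used here name no genome build for the probes. A probe counted as detected at a detection p under 0.05 in at least 3 of the 6 arrays. Each gene was represented by its brightest probe by mean over the 6 arrays and was left out if that probe was not detected. This left 9808 of 19057 named genes for testing. Arrays give no read depth, and with 3 arrays per group their number limits the precision.

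Groups were compared with limma (lmFit and eBayes, group as the only term) and Benjamini-Hochberg adjustment over the 9808 genes, with an adjusted p under 0.05 as the threshold. Log2 fold changes are shChd4 minus control, with the moderated standard error (SE). For a gene not detected on any array of 1 group, the fold change is given as a bound ("at least"). The bound sets the mean of the bright group against the mean, over the arrays of the dim group, of the lowest signal among detected probes or the probe's own signal if higher. In each of 31 gene lists fixed in advance, genes were tested as a group with camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists. Camera asks whether the members moved relative to all other genes tested. The same test with the correlation estimated from the 6 arrays, and the rotation test fry, were alternatives.

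The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named Chd4, the 10 largest rises and 10 largest falls with adjusted p under 0.05 and groups that did not overlap, and up to 4 members of each list with the smallest p. It also named Pou5f1, Sox2, Nanog, Chd1, Chd2, Chd6, Chd8, Chd9, Ep400, Smarca4 and Mbd3 whatever their values. Symbols of unnamed gene models were to be left out of the largest changes; this removed 0 among the rises and 1 among the falls. Genes named outside the rule are listed at the start of the other observations.

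The steps were tested on simulated arrays built from the control intensities, with 200 probes changed by known amounts, a further list of 20 genes raised by 0.8 on the log2 scale, and 11933 genes in the test. Rises of 2 on the log2 scale were called for 33 of 33 genes and falls of 2 for 27 of 34; of the 7 missed, 3 were not among the genes tested and 4 did not pass. At a log2 change of 1, 30 of 33 rises and 28 of 34 falls were called, and at 0.5 only 5 of 33 rises and 0 of 33 falls. Of 138 calls, 123 were among the changed probes, 11 were in the raised list and 4 were false (2.90%). Estimated changes had a median of 0.93 of the true value at a log2 change of 2.

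Alternatives were no background correction, scaling to a common median in place of quantile normalisation, the authors' normalised values, an offset of 50, 3 other detection filters, the mean of a gene's detected probes, a trended robust variance model, array weights, and leaving out each array in turn. A fit with the BeadChip as a block was not possible because each chip holds 1 group.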

Results

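Chd4 is the ATPase of the NuRD complex, which couples nucleosome remodelling to histone deacetylation. The series title places this experiment in a survey of chromatin remodellers in mouse ES cells, and the comparison asks which transcripts differ after transfection of an shRNA against Chd4. Transcript levels were measured on 3 control and 3 shChd4 arrays. Of the 45281 probes, 15817, 15909 and 16120 were detected on the control arrays and 17522, 17070 and 17141 on the shChd4 arrays. That is 34.9% to 35.6% of probes in controls and 37.7% to 38.7% after Chd4 shRNA. Across the genes tested, which are not independent replicates, arrays of one group correlated with r from 0.983 to 0.989. Arrays of different groups correlated with r from 0.915 to 0.950.

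The Chd4 transcript was lower on every shChd4 array. Its brightest probe gave log2 intensities of 10.13, 10.13 and 10.17 on the control arrays and 8.06, 7.91 and 8.33 on the shChd4 arrays. The log2 fold change was -2.04 ± 0.16 (SE, n = 3 per group; limma adjusted p = 6.33e-06), which leaves 24.3% of the control intensity. Further Chd4 probes detected on all 6 arrays changed by -1.86 and -1.26. A further probe, detected on 2 arrays and close to background, changed by 0.34.

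**Figure D1:**
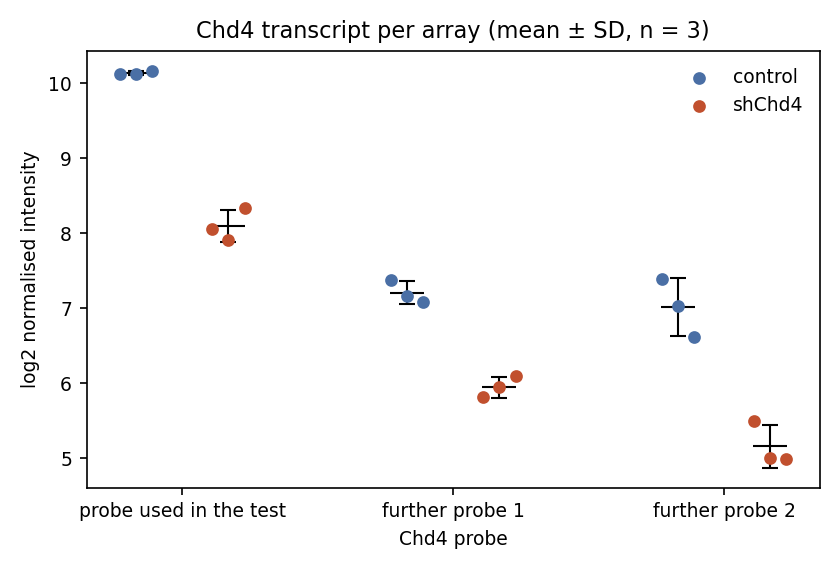
Log2 normalised intensity (vertical axis) of the 3 Chd4 probes detected on all 6 arrays (horizontal axis); points are arrays, coloured by group, and bars show the mean ± SD of 3 arrays. All shChd4 arrays lie below all control arrays for each probe, with the tested probe at 10.14 in controls and 8.10 after Chd4 shRNA on average.

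In total 3735 of the 9808 genes tested changed, 1947 higher and 1788 lower after Chd4 shRNA. Changes of at least 2-fold were made up of 864 rises and 375 falls. Of the genes that rose at least 2-fold, 135 were not detected on any control array, and 10 of those that fell were not detected on any shChd4 array. At an unadjusted p under 0.05, 4633 genes passed, where chance alone gives 490.4. The count of changes of at least 2-fold depended on the background step: without background correction it was 430, with 338 rises and 92 falls.

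The 10 largest rises by the naming rule began with Saa3 and Ccl5. Saa3, an acute-phase protein, rose by a log2 fold change of 5.74 ± 0.27 (SE; limma adjusted p = 3.90e-07), and the chemokine gene Ccl5 rose by 5.56 ± 0.20 (limma adjusted p = 7.11e-08). The matrix metalloproteinase genes Mmp3 and Mmp13 rose by 5.56 and 4.44. Another detected Mmp13 probe rose by 3.13, whereas a dimmer one, close to background, changed by -0.03. The matrix genes Dcn, Mgp, Thbs2 and Tnc rose by 5.39, 5.31, 4.57 and 4.30. The brightest other Tnc probe rose by 4.42, and dimmer detected Tnc probes changed by 0.54 and 1.58. Lcn2, a secreted iron-siderophore carrier, was not detected on any control array and rose at least 13.9-fold. B2m, the light chain of MHC class I, rose by 4.23 on its tested probe and by 4.08 on another. For these 10 genes the limma adjusted p was at most 1.56e-05.

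The 10 largest falls by the same rule began with Myo1f and Fgf17. Myo1f, an unconventional myosin, fell by 3.24 on the log2 scale (SE 0.29; limma adjusted p = 1.36e-05), and Fgf17, a fibroblast growth factor, fell by 3.05 (SE 0.22; limma adjusted p = 4.00e-06). Bdh2, Pold2 and Gli2 had log2 fold changes of -2.97, -2.92 and -2.80, and Cobl and Actn3 of -2.60 and -2.59. Pold2 encodes a subunit of DNA polymerase delta, and Gli2 a transcription factor of Hedgehog signalling. For Dnajc6, Tnfsfm13 and the amino acid transporter gene Slc7a3 the log2 fold changes were -2.55, -2.40 and -2.35. The limma adjusted p of these 10 genes was at most 0.000167.

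Of the 31 gene lists, 13 moved as a group by camera at the preset correlation, 10 up and 3 down. With an estimated correlation 0 lists passed; the lowest adjusted p was 0.242, and 6 lists had an unadjusted p under 0.05. The rotation test fry, which does not compare a list with other genes, called 23. Its further 10 were the naive pluripotency, NuRD, Polycomb, DNA methylation, LIF-STAT3, Wnt, TGF-beta and BMP, trophectoderm, imprinted and oxidative phosphorylation lists. In what follows, a list's camera adjusted p is at the preset correlation, followed by the adjusted p with an estimated correlation.

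**Figure D2:**
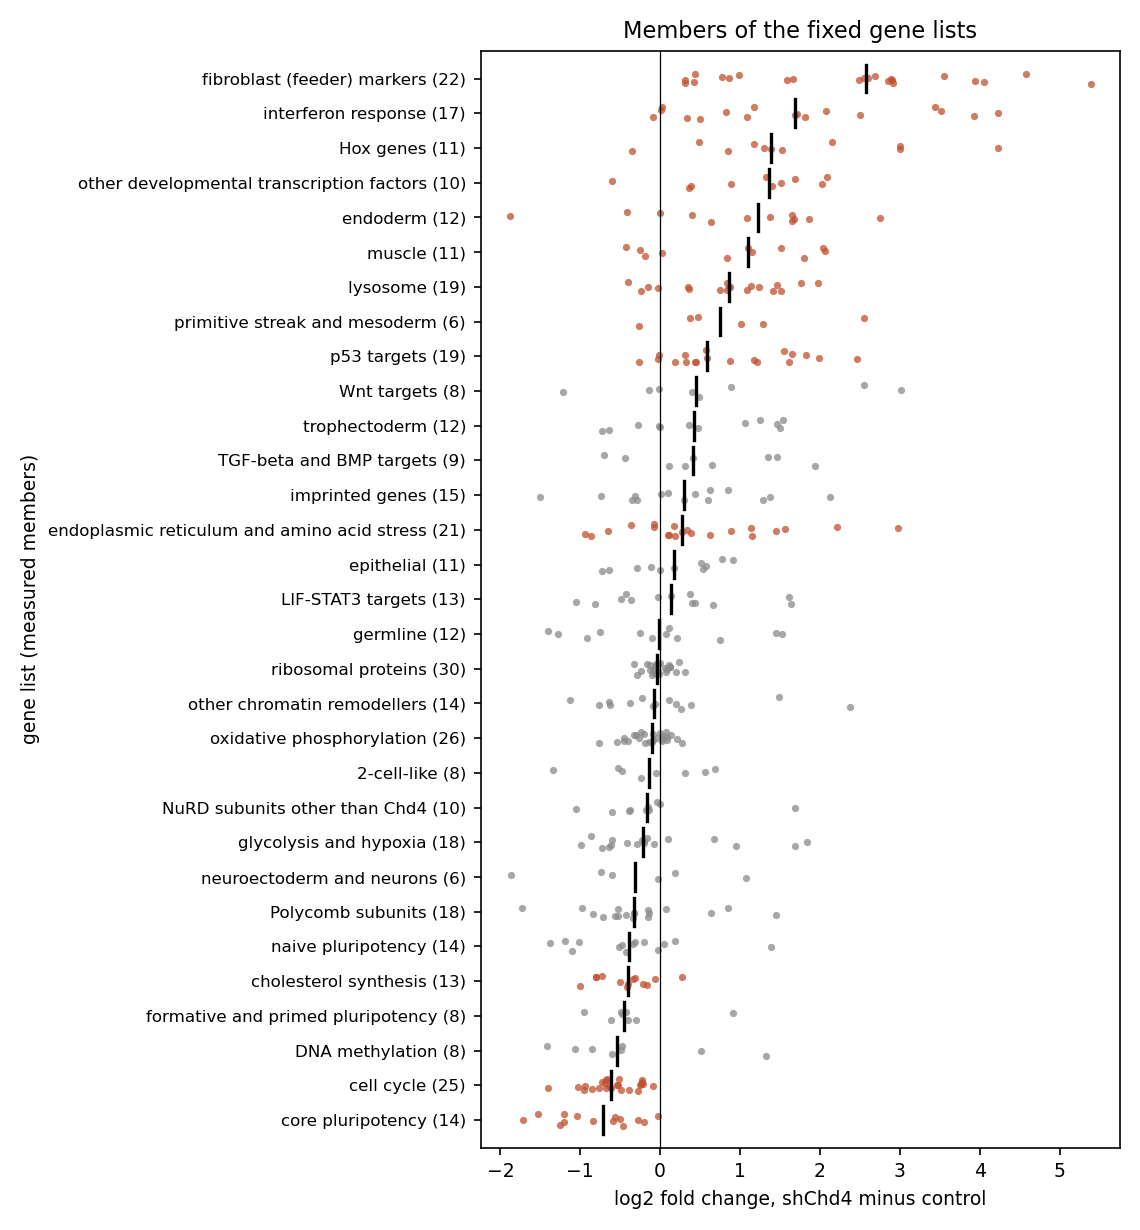
Log2 fold change, shChd4 minus control (horizontal axis), of the measured members of the 31 gene lists (vertical axis, with the number measured in parentheses); points are genes, black bars are list medians, and lists called by camera at the preset correlation are in red. Medians run from -0.72 for core pluripotency to 2.58 for the fibroblast markers.

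Fibroblast markers moved most. Of 22 measured markers of fibroblasts, the cell type of the feeder layer, 19 rose and 0 fell (20 rises adjusted over the list alone), with a median log2 change of 2.58. The camera adjusted p was 5.78e-14, and the adjusted p = 0.242 with an estimated correlation. Beside Thbs2 and Dcn, the small leucine-rich proteoglycan gene Lum rose at least 8.64-fold from below detection in controls, and the transcription factor gene Twist2 rose by 2.89 ± 0.19 (SE; limma adjusted p = 2.81e-06). A second Dcn probe rose by 4.16, and a second Lum probe by 0.98. The list mean was 6.04, 6.44 and 6.58 on the control arrays and 8.76, 8.44 and 8.78 on the shChd4 arrays, so shChd4 replicate 2 was the lowest of its group. Of the 849 genes outside this list that rose at least 2-fold, 67.1% were likewise lowest on that array among the shChd4 arrays, against 33.2% of all genes tested, so the order of arrays given below is not particular to single lists.

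Interferon response genes rose beside the fibroblast markers. Of 17 measured, 12 rose and 0 fell (13 rises adjusted over the list alone), with a median of 1.69, or 1.43 with 4 undetected genes at their bound. By camera the adjusted p was 9.13e-08, and the adjusted p = 0.242 with an estimated correlation. The ubiquitin-like modifier gene Isg15 rose by 3.43 ± 0.18 (SE; limma adjusted p = 6.89e-07). Ifit3 and Ifi27 rose by 3.51 and 3.93, and the transcription factor gene Irf7 rose at least 2.69-fold. The fibroblast list rose by a median of 2.58 on the same arrays, and shChd4 replicate 2 had the lowest mean of its group for both lists. The interferon mean was 8.03, 7.71 and 7.73 on shChd4 replicates 1, 2 and 3. Replicate 3, with the highest fibroblast mean, thus lay close to replicate 2.

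Developmental transcription factor genes rose as well. Of 11 measured Hox genes, 9 rose and 0 fell (10 rises and 1 fall adjusted over the list alone), with a median of 1.39. For 5 of the 11, no array of 1 group reached detection. The detection filter let these in only through the group where they were higher, so their direction is not independent of it. At the preset correlation the camera adjusted p was 3.59e-06, and the adjusted p = 0.242 with an estimated correlation. Hoxc6 rose by 4.22 ± 0.27 (SE; limma adjusted p = 2.28e-06) and was detected on 1 control array. Hoxb7 rose by 3.00, Hoxc9 at least 6.27-fold and Hoxa5 at least 3.10-fold. Of 10 other developmental transcription factor genes, 7 rose and 0 fell (7 rises and 1 fall adjusted over the list alone), with a median of 1.36, or 1.14 with 2 genes at their bound. Its camera adjusted p was 0.000257, and the adjusted p = 0.242 with an estimated correlation. Irx3 rose by 2.08, and Foxc1 and Meis1 rose at least 2.28-fold and 2.15-fold. En1 rose by 2.03 on its tested probe, whereas another detected En1 probe changed by 0.08. With only genes detected on all 6 arrays, this second list's adjusted p was 0.0511, and the Hox list kept too few genes to be tested. In both lists, too, shChd4 replicate 2, the array of its group with the lowest fibroblast mean, had the lowest mean.

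Lineage markers changed unevenly. Of 12 endoderm genes, 8 rose and 1 fell, with the same counts adjusted over the list alone. The median was 1.23, or 1.15 with 2 genes at their bound; the camera adjusted p was 0.00442, and the adjusted p = 0.242 with an estimated correlation. The basement membrane genes Col4a2 and Sparc rose by 2.75 and 1.68, Pdgfra rose at least 2.32-fold, and the laminin gene Lama1 fell by 1.88 on the log2 scale. Col4a2, Sparc and Pdgfra are also expressed by fibroblasts. With only genes detected on all 6 arrays the endoderm adjusted p was 0.0501.

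Of 11 muscle genes, 7 rose and 0 fell, also when adjusted over the list alone, with a median of 1.10, or 0.91 with 2 genes at their bound. As a list they gave a camera adjusted p of 0.0129, and the adjusted p = 0.289 with an estimated correlation. Myl9 rose by 2.06, Acta2 by 1.80, Tnnc1 by 1.15 and Actc1 at least 1.88-fold. The muscle call held in 13 of 16 alternatives at the preset correlation (adjusted p 0.00807 to 0.0835) and was lost with only genes detected on all 6 arrays (0.0501), without shChd4 replicate 1 (0.0518) and without shChd4 replicate 2 (0.0835). Of 6 primitive streak and mesoderm genes, 3 rose, namely Cdx1 (2.55), Snai1 (1.29) and Bmp4 (1.01), also when adjusted over the list alone. The median was 0.75 and the camera adjusted p 0.0455, with adjusted p = 0.360 with an estimated correlation. That call held in 7 of 14 alternatives at the preset correlation (adjusted p 0.0101 to 0.124) and was lost without control replicate 1 (0.0706), control replicate 2 (0.0523) or shChd4 replicate 2 (0.0561). Without shChd4 replicate 1 the median was 1.16. The call was also lost with array weights (0.0508), without background correction (0.0634; median 0.32), with the authors' values (0.0633; median 0.33) and without a detection filter (0.124; median 0.07). Among the shChd4 arrays, Col4a2, Sparc, Pdgfra and Acta2 were lowest on replicate 2, like the fibroblast mean, while the means of the muscle, primitive streak and endoderm lists were highest there.

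Target genes of p53 rose. Of 19 measured, 9 rose and 0 fell (10 rises adjusted over the list alone), with a median of 0.59. The camera adjusted p was 7.40e-05, and the adjusted p = 0.289 with an estimated correlation. The cell cycle inhibitor gene Cdkn1a rose by 2.47 ± 0.17 (SE; limma adjusted p = 3.49e-06), Phlda3 by 1.99, Plk2 by 1.65 and Mdm2, which encodes the ubiquitin ligase of p53, by 1.54. Lysosomal genes had 13 rises and 0 falls among 19 (13 rises and 1 fall adjusted over the list alone), with a median of 0.86. By camera the adjusted p was 7.40e-05, and the adjusted p = 0.289 with an estimated correlation. Sqstm1, Cd63, Lamp2 and Ctsb rose by 1.97, 1.76, 1.51 and 1.46, and 1 of the other detected Lamp2 probes changed by 0.02. The list means of both groups of genes were lowest on shChd4 replicate 2 among the shChd4 arrays, like the fibroblast mean.

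Of 21 genes of endoplasmic reticulum and amino acid stress, 7 rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 0.28. At the preset correlation the camera adjusted p was 0.0455, and the adjusted p = 0.472 with an estimated correlation. Ddit3, a stress-induced transcription factor gene, rose by 2.98, Ddit4 by 1.57 and Dnajb9 by 1.15. Slc7a11, which encodes a cystine transporter, rose at least 3.69-fold, and another detected probe of it changed by 0.82. The call held in 8 of 16 alternatives at the preset correlation (adjusted p 0.0126 to 0.268) and was lost without control replicate 3 (0.115) and without shChd4 replicate 1 (0.268; median 0.10), 2 (0.0507; median 0.14) or 3 (0.0900). It was also lost with median scaling (0.0775; median 0.19), with array weights (0.0513), with only genes detected on all 6 arrays (0.0923; median 0.19) and at a detection p under 0.01 (0.0773). The list mean of shChd4 replicate 2, the array of its group with the lowest fibroblast mean, was the lowest of its group at 9.01, against 9.49 and 9.28. Among the control arrays, however, the list mean was lowest on replicate 3 (8.66), where the fibroblast mean was highest.

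Of 14 core pluripotency genes, 9 fell and 0 rose (10 falls adjusted over the list alone), with a median of -0.72. As a list they gave a camera adjusted p of 0.000317, and the adjusted p = 0.289 with an estimated correlation. Pou5f1, which encodes Oct4, fell by 1.26 on the log2 scale (SE 0.21; limma adjusted p = 0.00101), and Nanog fell by 0.84 (SE 0.23; limma adjusted p = 0.0148). A second Nanog probe changed by -1.52. Without shChd4 replicate 3 the Nanog change was -0.56, and without a detection filter its adjusted p was 0.0575 (0.00324 to 0.0575 over its alternatives). Sox2 changed by -0.57 ± 0.25 (SE) and did not pass (limma adjusted p = 0.0977), but passed without shChd4 replicate 3 (-0.84, adjusted p = 0.0198; 0.0198 to 0.410 over its alternatives). A dimmer Sox2 probe, close to background and detected on 4 arrays, changed by 0.12. Gdf3, Fgf4 and Dppa2 fell by 1.71, 1.52 and 1.20. Of 14 naive pluripotency genes, 4 fell and 1 rose (5 falls and 1 rise adjusted over the list alone), with a median of -0.38. This list did not pass (camera adjusted p = 0.0665), but passed in 3 of 16 alternatives (0.0166 to 0.215 over all): with median scaling (0.0166), without a detection filter (0.0429) and without control replicate 1 (0.0352). Jam2, Tcl1 and Prdm14 fell by 1.38, 1.20 and 1.10, whereas Dppa3 rose by 1.39 ± 0.23 (SE; limma adjusted p = 0.000907). On the same arrays the fibroblast list rose by a median of 2.58, and the core pluripotency mean of shChd4 replicate 2 was the highest of its group at 9.70. The naive mean was also highest there among the shChd4 arrays (9.65). From control replicate 1 to 3 the fibroblast mean rose, the core mean fell (10.4, 10.3 and 10.1) and the naive mean rose (9.80, 9.90 and 9.98).

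Cell cycle genes fell by a median of 0.62 on the log2 scale, with 16 falls and 0 rises among 25 (17 falls adjusted over the list alone). The camera adjusted p was 9.51e-06, and the adjusted p = 0.242 with an estimated correlation. The replication licensing gene Cdc6 fell by 1.40, and Aurkb, Mcm3 and Tyms by 1.02, 0.95 and 0.94. Of 3 further detected Tyms probes, 1 changed by -1.13, 1 by -0.02 and 1 by 0.38. The fibroblast markers, which belong to a feeder cell type blocked in division, were higher on the same arrays by a median of 2.58. Cholesterol synthesis genes had 5 falls and 0 rises among 13, with the same counts adjusted over the list alone and a median of -0.40. By camera the adjusted p was 0.0345, and the adjusted p = 0.456 with an estimated correlation. Lss and Sqle fell by 1.00 and 0.80, although a second Lss probe changed by 0.11. The cholesterol call held in 6 of 16 alternatives at the preset correlation (adjusted p 0.0105 to 0.118) and was lost without control replicate 1 (0.0788; median -0.26) or 3 (0.115), and without shChd4 replicate 1 (0.0518), 2 (0.0835) or 3 (0.0563). It was also lost without background correction and with the authors' values (0.0505 each, median -0.20), with array weights (0.0701), with only genes detected on all 6 arrays (0.118) and at a detection p under 0.01 (0.0773).

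**Figure D3:**
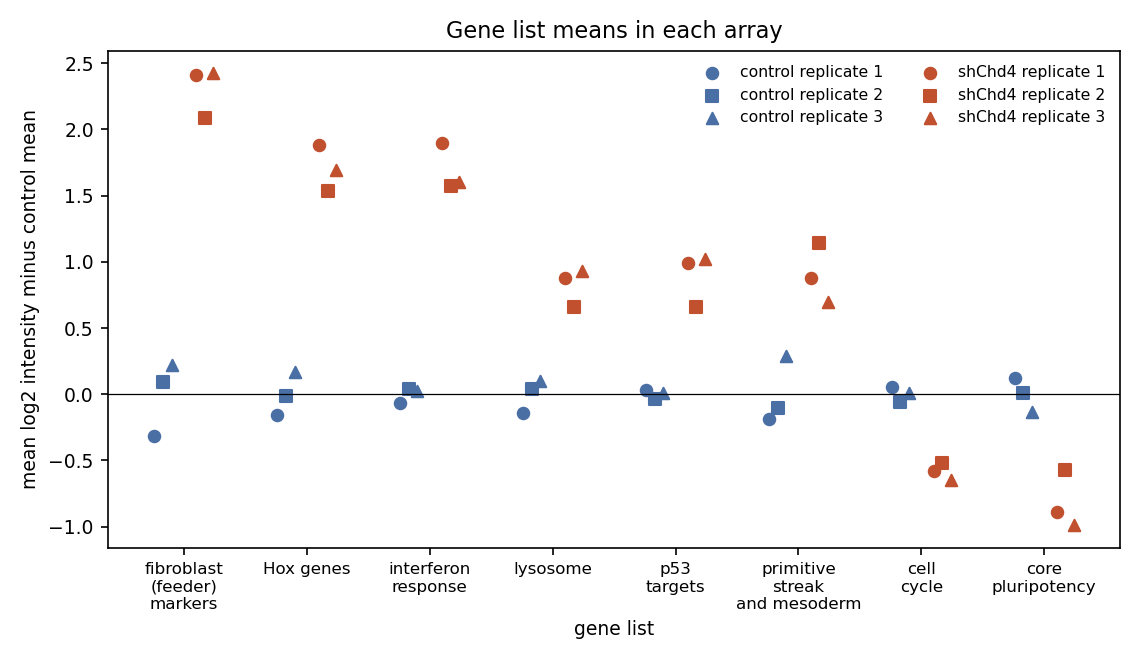
Mean log2 intensity of the measured members of 8 gene lists on each array, minus the control mean (vertical axis), by list (horizontal axis); colours are groups and symbols are arrays. The fibroblast mean was 8.44 on shChd4 replicate 2 and 8.76 and 8.78 on the other shChd4 arrays, against 6.04 to 6.58 in controls.

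Other NuRD subunits did not move as a group (camera adjusted p = 0.342), with 1 rise and 2 falls among 10, also adjusted over the list alone. Chd3, a paralog of Chd4 that can take its place in NuRD, rose by 1.69 ± 0.18 (SE; limma adjusted p = 4.41e-05). Rbbp4 fell by 1.05 on its tested probe, while another detected probe changed by -0.03. Mbd3 changed by -0.39 ± 0.15 (SE) and did not pass (limma adjusted p = 0.0592), but passed in 9 of 16 alternatives (0.0103 to 0.155), none of which left out an array. Among 14 other chromatin remodellers 2 rose and 4 fell (camera adjusted p = 0.941), also adjusted over the list alone. Smarca2 and Chd5 rose by 2.38 and 1.48, and Smarcad1 fell by 1.12 on the log2 scale. Other detected Chd5 probes changed by 0.25 and 1.09. Chd9 fell by 0.64, a call that was lost without control replicate 1 (adjusted p = 0.0797), control replicate 2 (0.0804) or shChd4 replicate 3 (0.0649). That call was also lost with the mean of its probes (-0.29, adjusted p = 0.148). Another Chd9 probe detected on all 6 arrays changed by -0.68, and dimmer detected probes by 0.23 and -0.08. Smarca4, which encodes Brg1, fell by 0.63 (limma adjusted p = 0.0404). That call was lost in 5 of the 6 fits that left out 1 array, with adjusted p up to 0.129 and a change of -0.37 without shChd4 replicate 1, and held without shChd4 replicate 2; it was also lost without a detection filter (0.105). Chd1, Chd2, Chd6, Chd8 and Ep400 did not pass, with changes of -0.22, -0.09, 0.26, -0.06 and 0.39 and limma adjusted p of 0.443, 0.686, 0.198, 0.786 and 0.0916. Ep400 passed in 4 of 16 alternatives (0.0411 to 0.263): without background correction, with the authors' values, with an offset of 50 and with the trended robust variance model.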

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

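The fit with the fibroblast marker mean as a covariate was chosen after seeing the data; all others were fixed before the data were examined. The count of changed genes (3735) stayed within 1.5 times under all 16 of those that apply to it, from 2803 to 3935, and the Chd4 change lay between -2.17 and -1.69, always past the threshold. Median log2 changes over all genes differed from that reported (-0.05) by under 0.1 in each. Changes of at least 2-fold were fewer without background correction or with the authors' values (430 each, 338 rises and 92 falls) and with an offset of 50 (761, with 561 and 200), settings that by construction compress dim genes. With only genes detected on all 6 arrays, where 7970 genes were tested, 573 rose at least 2-fold. That filter left 6 lists called, 4 of them up. Estimated correlations left 0 lists, 0 up and 0 down, with 6 at an unadjusted p under 0.05, and fry called 23, 8 of them down. Median scaling gave 6 lists down and no detection filter 5; the cause was not tested. Leaving out 1 array at a time gave 2803 to 3381 changed genes, 1092 to 1354 of at least 2-fold, 9 to 12 lists and a Chd4 change from -2.17 to -1.95. Chd1 and Chd8, not called in any case, changed sign, with ranges of -0.36 to 0.0038 and -0.16 to 0.040; the cause was not tested. With the covariate, 0 genes passed in limma (497 at an unadjusted p under 0.05), and Chd4 gave -2.77 ± 0.98 (SE, adjusted p = 0.934). The call ended because 97.2% of the covariate's variance lay between the groups, which raised the median SE from 0.18 to 1.04, so this fit says nothing of stability. Over the named genes, 2200 results under an alternative kept direction and side of the threshold, 79 fell short of it, 34 newly passed and 2 reversed. Most named genes were picked from these data by largest change or smallest p, so this count is no independent check. Fits without background correction and with the authors' values gave nearly the same results (3656 and 3655 changed genes). They are close to 1 alternative in each count of alternatives. No paired analysis was possible because the labels give no replicate numbers, and the BeadChip block was not run because each chip holds 1 group. Low signal over background leaves only a bound for 135 of the genes that rose at least 2-fold and 10 of those that fell.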

Other observations

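The search of gene families by symbol was chosen after the results were seen, as were the tests of array pairs, second probes and pluripotency intervals below; the counts over other splits of the arrays were planned before they were seen. Outside the rule for naming genes, Bgn, Mmp2, Col1a1, Col1a2, Col3a1, Col5a1, Col5a2, Col6a1, Postn, Fap, Zfp42, Dppa5a, Fbxo15, Klf4 and Klf5 were chosen after their values were seen. Among 150 families with at least 8 tested genes, 4 held more rises of at least 2-fold than the other genes tested (one-sided Fisher's exact test, Benjamini-Hochberg over 300 tests). Matrix metalloproteinase genes had 7 such rises among 11 (adjusted p = 0.0029), collagen genes 9 among 22 (0.00797), Ccl chemokine genes 5 among 8 (0.0234) and genes named Cd 10 among 34 (0.037). Of these rises Mmp2, Col1a1, Col5a1 and Col6a1 are also fibroblast markers, a list that rose by a median of 2.58 on the same arrays. No family passed among the falls. Families here are shared symbol stems, so members such as the genes named Cd need not be related. Fisher's test treats genes as independent, which genes on the same 6 arrays are not, so these p-values may be too small. Of 8 measured targets of Wnt signalling 4 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.45, or 0.28 with 1 gene at its bound (camera adjusted p = 0.0790). Sp5 rose by 3.02 ± 0.23 (SE; limma adjusted p = 6.03e-06) and Cdx1 by 2.55. Of 9 targets of TGF-beta and BMP signalling 3 rose, Id1, Id2 and Id3 (1.35, 1.94 and 1.47), and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0789). Of 12 trophectoderm genes 5 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.0789), among them Rhox9, Fgfr2 and Tfap2c with rises of 1.54, 1.46 and 1.24; another detected Fgfr2 probe changed by 0.53. The trophectoderm list passed with median scaling (0.0475), without a detection filter (0.0383; median 0.08) and without shChd4 replicate 3 (0.0246), with 0.0246 to 0.138 over 16 alternatives. Imprinted genes went both ways, with 6 rises and 2 falls among 15, also adjusted over the list alone (camera adjusted p = 0.230). Igf2 rose by 2.12, Ndn by 1.37 and Igf2r by 1.29, and Phlda2 fell by 1.51 on the log2 scale.

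The following lists did not pass as groups by camera at the preset correlation. In alternatives, Polycomb subunits passed without a detection filter (adjusted p = 0.0429), and oxidative phosphorylation and ribosomal protein genes passed with median scaling (0.0117 each, medians -0.32 and -0.27). Polycomb subunits had 3 rises and 7 falls among 18, also adjusted over the list alone (camera adjusted p = 0.0954), with Phc1 lower (-1.73) and Phc2 higher (1.44). DNA methylation genes had 1 rise and 5 falls among 8 (2 and 5 adjusted over the list alone; camera adjusted p = 0.156), with Tet1 and Uhrf1 at -1.41 and -1.06. Glycolysis and hypoxia genes had 4 rises, Vegfa (1.83) and P4ha2 (1.69) among them, and 6 falls among 18, also adjusted over the list alone (camera adjusted p = 0.402). LIF-STAT3 targets had 4 rises and 2 falls among 13 (5 and 2 adjusted over the list alone; camera adjusted p = 0.583), with Junb and Osmr at 1.64 and 1.61. Germline genes had 3 rises and 4 falls among 12, also adjusted over the list alone (camera adjusted p = 0.802), with Taf7l at 1.53 and Tuba3a at -1.40. Neuroectoderm genes had 1 rise and 2 falls among 6, also adjusted over the list alone (camera adjusted p = 0.449), with Stmn2 at -1.86. Formative pluripotency genes had 1 rise and 2 falls among 8, also adjusted over the list alone (camera adjusted p = 0.230). Epithelial genes had 3 rises and 1 fall among 11 (5 and 2 adjusted over the list alone; camera adjusted p = 0.449), and genes of the 2-cell-like state 2 and 1 among 8, also adjusted over the list alone (camera adjusted p = 0.941). Oxidative phosphorylation genes had 3 falls among 26 (0 adjusted over the list alone; camera adjusted p = 0.276), and ribosomal protein genes 0 changes among 30 by limma, with a median of -0.04 (camera adjusted p = 0.802).

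The large number of changed genes has no test that separates it from handling. The 2 BeadChips hold 1 group each, so 0 chips carry both groups, and differences in chip, labelling or culture day cannot be told apart from the shRNA. No other shRNA group was measured, so loss of Chd4 cannot be told apart from other effects of this shRNA. Artifacts of single probes are argued against for the 405 genes changed at least 2-fold that had another detected probe. Of these, 95.1% changed in the same direction on it (exact binomial 95% interval 92.5 to 97.0). That interval treats genes on the same 6 arrays as independent, and genes without another detected probe were not tested in this way. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split, 1 of 10, gave 3735 changed genes and 1239 of at least 2-fold against 0 and 0 in the highest other split. For lists 2 of the 10 splits gave as many, with 13 in the real and 14 in the highest other split. Every other split mixes arrays of both groups, so the group difference enters its spread whatever the cause. These counts therefore decide nothing.

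A candidate explanation for the rise of fibroblast markers with Hox, interferon, lysosomal and p53 target genes is a larger share of feeder fibroblast RNA in the shChd4 arrays; the cells had 48 h of puromycin, and the labels give no sort and do not say whether the feeders resist it. The 849 genes outside the fibroblast list that rose at least 2-fold were higher where the marker mean was higher, in 1 pair of arrays per group. Between the control arrays with the highest and lowest marker mean, their median log2 difference was 0.2677 (matched random lists -0.0037 to 0.048). Between such shChd4 arrays it was 0.2703 (random lists -0.049 to 0.0031). The random lists measure the choice of genes and not the spread between arrays. The 375 genes that fell at least 2-fold went the other way in the same pairs (-0.119 and -0.21). A gradient shared by all changed genes therefore cannot be told apart from feeder RNA. Col1a1 also rose, at least 4.39-fold from below detection in controls, and Bgn and Dcn had mean log2 levels of 13.64 and 11.65 after Chd4 shRNA (9.71 and 6.26 in controls), whereas Col1a2 and Col3a1, which feeder RNA should raise as well, differed by only 0.31 and 0.19 near background; whether their probes detect these transcripts is unknown, so this does not exclude it. Of the 30 markers 3 (Col5a2, Postn and Fap) were detected on no array, and of the 22 measured, 14 were detected on all control arrays and 0 are on another list. Transcription raised in ES cells by the depletion stays open too: the shChd4 array with the lowest Chd4 on the tested probe (7.91) had a smaller rise than the others (median -0.267), but the 2 other Chd4 probes detected on all 6 arrays were lowest on other arrays, so this decides nothing, and no pure ES cell or feeder sample was analysed here.

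Of the 28 measured core and naive pluripotency genes 13 fell and 1 rose. A lower share of ES cell RNA as the only cause would lower all of them alike if their probes responded equally. In 14 of them the 95% interval excluded the median change of -0.51, a count reached in a share of 0.0119 of random rotations of the arrays, which keep the correlation between genes (0.0103 without Dppa5a, which lay near the top of the intensity range at 14.84, and 0.0072 without Dppa5a, Klf4 and Klf5, the last 2 also expressed by fibroblasts). In 9 the fall was larger, Pou5f1, Gdf3 and Zfp42 among them, and in 5 it was smaller or absent (Dppa5a, Fbxo15, Klf4 and Klf5) or turned into a rise (Dppa3). An equal log2 fall on every probe is thus argued against. The rotations hold the spread between arrays but no difference in response between probes, and probes of 1 transcript also differed (Nanog, -0.84 and -1.52). The test therefore cannot exclude 1 common dilution, which may account for part or all of the falls. A lower share of ES cell RNA would not by itself raise Dppa3, so it leaves that rise unexplained. A response of ES cells to Chd4 depletion stays open as an untested explanation, as does the BeadChip.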
